A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

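Total RNA from Saccharomyces cerevisiae was extracted with phenol, labelled with biotin and hybridized to Affymetrix yeast arrays, per the labels' protocols. The deposited values are log2 signal per probe set, with 1 column per array for 21 arrays. The submitters' processing notes name affy and RMA, with no version, and steps beyond those names are not given in the sources used here. RMA subtracts background, applies quantile normalization and summarises probes, and quantile normalization forces the arrays to 1 distribution, so a change shared by most genes would not show. The groups, replicate numbers and treatment times were taken from the sample titles and descriptions, before the data were examined, as were the comparisons, gene lists, named-gene rule and all alternative settings other than the 1 named in the closing section as added later.

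The value table holds 10928 probe sets and no missing value. Of the 7245 that the probe annotation lists, 5498 carried 1 S. cerevisiae gene, 1746 carried 1 gene whose identifier is not among those of S. cerevisiae and was taken to be of another species, and 1 carried several and was left out. A further 213 were control or reporter probe sets and 3470 had no name here. Names were updated through the gene identifier for 12 symbols, with a gene table of assembly R64, from which no coordinates were used. For the 47 genes with more than 1 probe set, the one with the highest mean was used, which left 5449 genes, 97 of them measured by probe sets named _s_at and 16 by ones named _x_at, which can also bind related transcripts. The other-species probe sets had a median of 3.94 and served as background, with their 95th percentile, 4.84, as limit; 5357 genes had a mean above it, and 97.2% to 99.0% of genes did so on each array. POX1 in the control groups lay near that limit.

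Each comparison was a contrast in 1 group-means model over all 21 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 14 residual degrees of freedom), with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. An exact test of 3 arrays against 3 cannot go below 0.1, so no single-gene permutation test was made. Gene lists, 31 in number, were tested against all other genes with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Calls of list members were also adjusted over the list alone. Correlations and the slope (Deming, equal errors) were taken across genes, with a jackknife over arrays for their standard error, and 3 of the correlations were chosen before the data were examined. For comparisons that share arrays, 100 simulations of unchanged groups gave the value with no effect, and a division of the shared arrays, 1 against 2, was added after seeing the data. Other splits of the arrays were counted, 10 for 3 arrays against 3 and 100 for each interaction.

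Named genes are, per comparison, up to 10 with the largest rise and up to 10 with the largest fall among those called whose replicates did not overlap between the groups (without the overlap condition for contrasts of 4 groups), up to 4 members of each list described with the largest change, called members first, and a set of control genes of sphingolipid synthesis, stress and fatty acid metabolism.

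Replicates within a group correlated with r between 0.993 and 0.998, and no pair shared more than 0.404% identical values, so each array was counted as 1 replicate. The replicate numbers come from the titles. Arrays of the same number deviated together, with every pair's correlation over 0.1, for ISP1 against control (0.230 to 0.530), heat with ISP1 against heat (0.172 to 0.433), heat with ISP1 against ISP1 (0.132 to 0.350) and myristate against the SC control (0.322 to 0.626), and not for the other comparisons. The first 3 principal components held 64.2%, 21.9% and 6.73% of the variance. The alternatives were a model of only the arrays compared, a replicate block, a filter on dim genes, quantile normalization or median centring over S. cerevisiae probe sets, an intensity trend with a robust prior, array weights, the mean of a gene's probe sets, a 2-fold minimum, leaving out each array, and Spearman's rank correlation.

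The contrast fit, the list test at the preset correlation, the slope and the correlation across genes were tested on simulated data. Noise was independent between genes, so p-values of lists whose members vary together were not tested. For the contrast fit 200 of the 5449 genes had known changes, and false calls were 2.47% to 7.43% of calls. The shares recovered hold for that number of changed genes and would be lower with fewer. A log2 change of 1 was recovered in 90% to 100% of genes in each comparison, and a change of 0.5 in 64% of genes for the heat by ISP1 interaction and in 76% to 90% of genes for contrasts of 2 groups. A list shifted by 0.5 was recovered at 0.492 in simulated heat against control, and a slope of 0.7 at 0.702.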

Results

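Transcript levels of the budding yeast Saccharomyces cerevisiae were measured on 21 Affymetrix yeast arrays, 3 in each of 7 groups. Cells in YPD, a rich medium of yeast extract, peptone and dextrose, formed 4 groups: control, heat stress, ISP1, and heat stress with ISP1. Cells in synthetic complete medium (SC) formed 3 groups: control, myristate, a saturated fatty acid, and myristate with ISP1. ISP1 is myriocin, per the series' design text, an inhibitor of serine palmitoyltransferase, the first enzyme of sphingolipid synthesis. Each treatment lasted 45 min per the labels, except myristate with ISP1, for which the labels give no time. In that group the descriptions of replicates 2 and 3 carry another number after ISP than their titles, and the groups follow the titles. Temperatures and doses are not given in the labels, nor is a vehicle for ISP1 or myristate, so it is not known whether the controls received one. The median level of the 5449 genes tested lay between 10.21 and 10.33 (log2) on every array, and replicates correlated across genes with r between 0.993 and 0.998. Differences are log2 fold changes ± standard error from limma with 3 arrays per group, and adjusted p-values are limma's after Benjamini-Hochberg. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

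The comparison of heated with unheated cells in YPD asked which transcripts respond to heat stress. YNL194C rose by 5.98 ± 0.18, a 63.0-fold increase, and ALD3, an aldehyde dehydrogenase gene, by 5.71 ± 0.14. HXT5, a hexose transporter gene, rose by 5.29 ± 0.18 and TKL2, a transketolase gene, by 5.29 ± 0.24. SOL4 (5.44 ± 0.12), FMP45 (5.38 ± 0.11), RTN2 (5.34 ± 0.10) and PHM7 (5.54 ± 0.17) rose to a like extent. The largest fall was that of HO, the mating-type switching endonuclease gene, from 12.09 ± 0.08 to 7.62 ± 0.23 (log2 level ± SD, n = 3). SFG1 (-4.27 ± 0.10), RNR1, which encodes a subunit of ribonucleotide reductase (-3.40 ± 0.08), and the ribosome biogenesis genes KRE33 (-3.60 ± 0.13) and DHR2 (-3.46 ± 0.12) fell as well.

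Stress genes rose together. Among the heat shock proteins and chaperones, 30 of 30 members rose (30 rises adjusted over the list alone), with a median of 2.07 (adjusted p = 2.65e-12, and adjusted p = 0.257 with an estimated correlation). HSP30, which encodes a plasma membrane protein, rose by 5.19 ± 0.12, the disaggregase gene HSP104 by 2.13 ± 0.07 and HSP26 by 3.52 ± 0.22. SSA4, an Hsp70 gene, went from 10.28 ± 0.29 to 14.95 ± 0.01 (SD, n = 3), near the top of the array's signal, as was HSP26 at 14.85 ± 0.01. Of the general stress genes, targets of the transcription factors Msn2 and Msn4, 30 of 31 members rose and 1 did not pass (30 rises adjusted over the list alone, adjusted p = 4.65e-13, and adjusted p = 0.257 with an estimated correlation). CTT1, the cytosolic catalase gene, rose by 4.85 ± 0.10. In trehalose and glycogen metabolism 18 of 20 members rose, 1 fell and 1 did not pass (18 rises and 1 fall adjusted over the list alone, adjusted p = 3.22e-07, and adjusted p = 0.257 with an estimated correlation). The glycogen phosphorylase gene GPH1 (4.59 ± 0.12) and the phosphoglucomutase gene PGM2 (4.33 ± 0.10) led the rises. Of the proteasome genes 32 of 32 members rose (32 rises adjusted over the list alone), with a median of 0.58 (adjusted p = 2.55e-07, and adjusted p = 0.257 with an estimated correlation). In endoplasmic reticulum folding 14 of 16 members rose, 1 fell and 1 did not pass (14 rises and 1 fall adjusted over the list alone, adjusted p = 0.000109, and adjusted p = 0.257 with an estimated correlation), with MPD1 at 2.29 ± 0.07.

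Genes of ribosome production and of the cell cycle fell. In ribosome biogenesis 67 of 67 members fell (67 falls adjusted over the list alone), with a median of -2.20 (adjusted p = 7.62e-18, and adjusted p = 0.288 with an estimated correlation). NOP7 changed by -3.13 ± 0.12. Among cytosolic ribosomal protein genes 1 of 127 members rose, 125 fell and 1 did not pass (1 rise and 125 falls adjusted over the list alone), and the median was smaller, at -0.81 (adjusted p = 6.87e-18, and adjusted p = 0.279 with an estimated correlation). For the G1/S cell cycle genes 17 of 20 members fell and 3 did not pass (17 falls adjusted over the list alone, adjusted p = 1.15e-05, and adjusted p = 0.257 with an estimated correlation). The cyclin genes CLB6 (-2.97 ± 0.12) and CLN2 (-2.66 ± 0.13) were among them. Of the G2/M and M/G1 genes 2 of 19 members rose, 16 fell and 1 did not pass (2 rises and 16 falls adjusted over the list alone, adjusted p = 0.000726, and adjusted p = 0.257 with an estimated correlation), including CLB2 (-2.89 ± 0.10) and CLB1 (-2.88 ± 0.08). In amino acid synthesis 5 of 43 members rose, 34 fell and 4 did not pass (5 rises and 34 falls adjusted over the list alone, adjusted p = 0.000120, and adjusted p = 0.462 with an estimated correlation). ARO9 rose by 2.93 ± 0.11.

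Lipid genes moved in both directions. The 2 genes of serine palmitoyltransferase fell, LCB1 (-0.51 ± 0.07) and LCB2 (-0.77 ± 0.07). Of the enzyme's regulators ORM2 rose by 1.36 ± 0.07 and ORM1 changed by -0.27 ± 0.07. The list of sphingolipid metabolism as a whole did not pass (adjusted p = 0.460), and 11 of 34 members rose, 17 fell and 6 did not pass (11 rises and 17 falls adjusted over the list alone). The ceramidase genes YPC1 (2.46 ± 0.06) and YDC1 (2.25 ± 0.06) were among its rises and the fatty acid elongase gene ELO2 (-2.01 ± 0.07) among its falls. In ergosterol synthesis 3 of 25 members rose, 19 fell and 3 did not pass (3 rises and 19 falls adjusted over the list alone, adjusted p = 0.00287, and adjusted p = 0.257 with an estimated correlation). In fatty acid beta-oxidation and peroxisome function 19 of 29 members rose, 6 fell and 4 did not pass (19 rises and 6 falls adjusted over the list alone, adjusted p = 0.0215, and adjusted p = 0.371 with an estimated correlation). The thiolase gene POT1 rose by 2.22 ± 0.25 and the acyl-CoA oxidase gene POX1 by 1.75 ± 0.22. In fatty acid synthesis, uptake and desaturation 2 of 13 members rose, 9 fell and 2 did not pass (2 rises and 9 falls adjusted over the list alone, adjusted p = 0.0473, and adjusted p = 0.260 with an estimated correlation). The desaturase gene OLE1 was at -2.08 ± 0.06. The call of that list was also lost under each of its other settings (adjusted p between 0.0512 and 0.0738).

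Over all genes, limma called 4394 of 5449 in heated against unheated cells, 2167 higher and 2227 lower, and 1488 of these changed at least 2-fold (715 higher and 773 lower). With median centring the balance turned, to 2289 higher and 2143 lower. The replicates of both groups did not overlap in 83.1% of genes, where chance gives 10%. Signs of RNA quality moved with heat. The 3' minus 5' signal was 0.38 ± 0.02 in control and 0.51 ± 0.03 with heat for actin (log2 ± SD, n = 3). It was 2.65 ± 0.11 and 3.01 ± 0.18 for SRB4, and 2.00 ± 0.18 and 2.30 ± 0.03 for SPT15. The poly-A controls, spiked transcripts that do not show RNA quality, averaged 7.35 ± 0.16 in control and 7.72 ± 0.11 with heat. The hybridization controls averaged 11.77 ± 0.23 and 11.74 ± 0.09. The cause of these shifts was not tested. Of the 31 lists, 17 passed with the preset correlation, among them also cell wall integrity targets (median 0.74, adjusted p = 0.00279, and adjusted p = 0.288 with an estimated correlation), the respiratory chain and ATP synthase (0.28, adjusted p = 0.00471, and adjusted p = 0.462 with an estimated correlation) and the TCA cycle (0.61, adjusted p = 0.00881, and adjusted p = 0.257 with an estimated correlation). With the estimated correlation no list passed, the lowest adjusted p being 0.257.

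The comparison of ISP1-treated with control cells in YPD asked what inhibition of sphingolipid synthesis does without heat. RTC2 rose by 3.50 ± 0.17, BDH2 by 3.45 ± 0.18 and the arginine synthesis gene ARG3 by 3.20 ± 0.30. CTT1 rose by 3.17 ± 0.10, an 8.99-fold increase, from 9.48 ± 0.32 to 12.65 ± 0.08 (SD, n = 3), and GPH1 by 3.04 ± 0.12. SNO1, of pyridoxine synthesis, rose by 3.07 ± 0.24. The steepest falls were in genes of phosphate supply: the acid phosphatase genes PHO5 (-3.19 ± 0.11), PHO11 (-3.17 ± 0.08) and PHO3 (-2.41 ± 0.11), and SPL2, a regulator of phosphate transport (-3.06 ± 0.10).

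Of the general stress genes 28 of 31 members rose and 3 did not pass (28 rises adjusted over the list alone), with a median of 1.56 (adjusted p = 9.73e-15, and adjusted p = 0.216 with an estimated correlation). In trehalose and glycogen metabolism 17 of 20 members rose, 1 fell and 2 did not pass (17 rises and 1 fall adjusted over the list alone, adjusted p = 8.97e-09, and adjusted p = 0.282 with an estimated correlation), with PGM2 at 2.81 ± 0.10 and GLC3 at 2.28 ± 0.18. The heat shock proteins and chaperones did not pass as a list (adjusted p = 0.779), and 7 of 30 members rose, 13 fell and 10 did not pass (7 rises and 13 falls adjusted over the list alone). Its test and median pointed down and its mean up. HSP12 rose by 1.84 ± 0.18 and HSP104 by 0.59 ± 0.07. HSP26 was at 0.47 ± 0.22 (adjusted p = 0.0671), and passed with the replicate number as a block (adjusted p = 0.0436). Over all of its settings that adjusted p ran from 1.59e-05 to 0.335, and it passed without control array 1 (5.86e-05) or ISP1 array 2 (0.0265). In amino acid synthesis 38 of 43 members rose and 5 did not pass (38 rises adjusted over the list alone, adjusted p = 4.39e-12, and adjusted p = 0.297 with an estimated correlation). The histidine synthesis gene HIS4 rose by 2.43 ± 0.17. In the phosphate regulon 1 of 13 members rose, 11 fell and 1 did not pass (1 rise and 11 falls adjusted over the list alone, adjusted p = 2.17e-05, and adjusted p = 0.184 with an estimated correlation).

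Ribosome biogenesis genes fell under ISP1 too: 67 of 67 members fell (67 falls adjusted over the list alone), with a median of -1.01 (adjusted p = 1.03e-17, and adjusted p = 0.366 with an estimated correlation). Cytosolic ribosomal protein genes did not pass as a list (adjusted p = 0.445), and 1 of 127 members rose, 9 fell and 117 did not pass (1 rise and 3 falls adjusted over the list alone). Mitochondrial ribosomal protein genes rose slightly, with a median of 0.18: 37 of 66 members rose, 1 fell and 28 did not pass (36 rises and 1 fall adjusted over the list alone, adjusted p = 8.25e-05, and adjusted p = 0.366 with an estimated correlation). In the respiratory chain and ATP synthase 26 of 36 members rose and 10 did not pass (26 rises adjusted over the list alone, adjusted p = 5.34e-05, and adjusted p = 0.376 with an estimated correlation). In the TCA cycle 11 of 14 members rose and 3 did not pass (12 rises adjusted over the list alone, adjusted p = 6.95e-05, and adjusted p = 0.107 with an estimated correlation). Among G1/S genes 18 of 20 members fell and 2 did not pass (18 falls adjusted over the list alone, adjusted p = 5.42e-05, and adjusted p = 0.327 with an estimated correlation). Among G2/M and M/G1 genes 15 of 19 members fell and 4 did not pass (15 falls adjusted over the list alone, adjusted p = 0.000567, and adjusted p = 0.297 with an estimated correlation).

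In the list of multidrug resistance transporters 10 of 16 members rose, 2 fell and 4 did not pass (10 rises and 2 falls adjusted over the list alone, adjusted p = 0.000574, and adjusted p = 0.187 with an estimated correlation). PDR15, an ABC transporter gene, rose by 1.70 ± 0.15, the polyamine transporter gene TPO4 by 1.67 ± 0.10 and YOR1 by 1.69 ± 0.07. ICT1, which rose by 1.61 ± 0.07, encodes no transporter but a lysophosphatidic acid acyltransferase. In sphingolipid metabolism 11 of 34 members rose, 10 fell and 13 did not pass (11 rises and 10 falls adjusted over the list alone), and the list did not pass (adjusted p = 0.232). RSB1, the sphingoid base transporter gene, rose by 1.43 ± 0.13, ORM2 by 0.71 ± 0.07 and the kinase gene YPK1 by 0.83 ± 0.05. LCB2 fell by 0.39 ± 0.07, whereas LCB1 was at -0.01 ± 0.07 (adjusted p = 0.911). In fatty acid beta-oxidation and peroxisome function 19 of 29 members rose, 3 fell and 7 did not pass (19 rises and 3 falls adjusted over the list alone, adjusted p = 0.00130, and adjusted p = 0.297 with an estimated correlation).

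In all, limma called 3331 in ISP1-treated against control cells, 1522 higher and 1809 lower, 454 of them by at least 2-fold (303 higher and 151 lower). Replicates did not overlap in 66.1% of genes (10% by chance). Of the 31 lists, 13 passed, including the proteasome at a median of 0.14 (adjusted p = 0.0184, and adjusted p = 0.603 with an estimated correlation), and none did with an estimated correlation.

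Heated cells with ISP1 were set against heated cells without it, to ask what ISP1 changes during heat stress. YGR035C, an uncharacterised gene, rose by 2.56 ± 0.22, and SPS100, a spore wall gene, by 2.27 ± 0.21. RSB1 rose by 1.97 ± 0.13 and RTA1, of the same protein family, by 2.22 ± 0.14. ICT1 went from 10.92 ± 0.03 to 12.73 ± 0.08 (SD, n = 3), a rise of 1.81 ± 0.07. SPL2 (-2.23 ± 0.10), PHM6 (-1.77 ± 0.11), PHO11 (-1.52 ± 0.08) and PHO5 (-1.45 ± 0.11) fell.

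The phosphate regulon fell, and the list kept its call with an estimated correlation: 10 of 13 members fell and 3 did not pass (11 falls adjusted over the list alone, adjusted p = 3.12e-11, and adjusted p = 0.0192 with an estimated correlation). The multidrug resistance transporters also kept theirs: 12 of 16 members rose, 2 fell and 2 did not pass (12 rises and 2 falls adjusted over the list alone, adjusted p = 7.57e-07, and adjusted p = 0.0294 with an estimated correlation). PDR15 rose by 1.30 ± 0.15, PDR5, another ABC transporter gene, by 1.00 ± 0.09, and PDR16, a phosphatidylinositol transfer protein gene, by 1.01 ± 0.07. In sphingolipid metabolism 11 of 34 members rose, 3 fell and 20 did not pass (13 rises and 4 falls adjusted over the list alone, adjusted p = 0.0394, and adjusted p = 0.487 with an estimated correlation). That call was also lost with quantile normalization over the genes of the species (adjusted p = 0.0680, with 0.0392 to 0.0680 over its other settings). IPT1, which makes the most complex sphingolipid of yeast, rose by 1.33 ± 0.06, SUR1 by 1.04 ± 0.12, ORM2 by 0.76 ± 0.07 and YPK1 by 0.53 ± 0.05. LCB1 rose by 0.19 ± 0.07 (adjusted p = 0.0353), a call lost with only the arrays compared (0.179) and without heat array 1 (0.196) or heat with ISP1 array 2 (0.134) or 3 (0.130), with adjusted p of 0.000352 to 0.196 over its settings. LCB2 was at 0.17 ± 0.07 (adjusted p = 0.0728), and passed with the replicate number as a block (adjusted p = 0.0420) or without heat array 1 (0.0434), with a range of 0.00657 to 0.291 over its settings.

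The general stress genes did not pass as a list: 5 of 31 members rose, 2 fell and 24 did not pass (5 rises and 1 fall adjusted over the list alone, adjusted p = 0.0834). CTT1 was at 0.12 ± 0.10 (adjusted p = 0.395). Nor did the heat shock proteins and chaperones pass (adjusted p = 0.0749), where 3 of 30 members fell and 27 did not pass (none adjusted over the list alone). HSP104 was at -0.03 ± 0.07 (adjusted p = 0.781). In ribosome biogenesis 55 of 67 members fell and 12 did not pass (59 falls adjusted over the list alone), with a median of -0.47 (adjusted p = 5.07e-15, and adjusted p = 0.506 with an estimated correlation). For the G1/S genes 17 of 20 members fell and 3 did not pass (19 falls adjusted over the list alone, adjusted p = 4.98e-10, and adjusted p = 0.135 with an estimated correlation). For the G2/M and M/G1 genes 15 of 19 members fell and 4 did not pass (15 falls adjusted over the list alone, adjusted p = 3.32e-08, and adjusted p = 0.0778 with an estimated correlation). PCL2, of the G1/S list, was at -1.40 ± 0.11, and CLB2, of the G2/M and M/G1 list, at -0.79 ± 0.10. Among cell wall integrity targets 3 of 24 members rose, 16 fell and 5 did not pass (3 rises and 17 falls adjusted over the list alone, adjusted p = 0.000102, and adjusted p = 0.287 with an estimated correlation), although GSC2, a glucan synthase gene, rose from 11.36 ± 0.12 to 12.86 ± 0.17 (SD, n = 3). In fatty acid beta-oxidation and peroxisome function 14 of 29 members rose, 2 fell and 13 did not pass (15 rises and 2 falls adjusted over the list alone, adjusted p = 0.00108, and adjusted p = 0.345 with an estimated correlation), with POT1 at 1.19 ± 0.25. The list of mating-type a cell markers, with a median of -0.35, did not pass (adjusted p = 0.0606) but did with the replicate number as a block (adjusted p = 0.0376, with 0.0376 to 0.0639 over its settings other than the estimated correlation).

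The count over all genes in limma was 1784 in this comparison, 898 higher and 886 lower, 78 of them by at least 2-fold (56 higher and 22 lower), and 2960 with array weights. More genes were lower than higher with the replicate number as a block (958 higher and 959 lower), quantile normalization (926 higher and 1019 lower), median centring (828 higher and 1014 lower) or an intensity trend and robust prior (901 higher and 917 lower), and without heat array 1 (810 higher and 883 lower) or heat with ISP1 array 2 (703 higher and 755 lower) or 3 (709 higher and 728 lower). Replicates did not overlap in 45.4% of genes (10% by chance). The 3' minus 5' signal of actin was 0.51 ± 0.03 with heat and 0.44 ± 0.01 with heat and ISP1 (SD, n = 3), and that of SRB4 3.01 ± 0.18 and 2.72 ± 0.09. For SPT15 it was 2.30 ± 0.03 and 2.19 ± 0.11. The remaining lists that passed, out of 11, were amino acid synthesis (median 0.17, adjusted p = 0.000825, and adjusted p = 0.723 with an estimated correlation), cytosolic ribosomal proteins (-0.09, adjusted p = 0.000212, and adjusted p = 0.723 with an estimated correlation) and the respiratory chain and ATP synthase (-0.11, adjusted p = 0.00805, and adjusted p = 0.723 with an estimated correlation).

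The interaction of heat and ISP1 tested whether the ISP1 difference changed between unheated and heated cells. It was lower in heated cells for genes that ISP1 alone had raised: ARG3 (-3.35 ± 0.43), RTC2 (-3.33 ± 0.24), GPH1 (-3.06 ± 0.17), CTT1 (-3.04 ± 0.15) and PGM2 (-2.76 ± 0.14). It was higher for genes that ISP1 alone had lowered, such as PHO5 (1.73 ± 0.15), PHO11 (1.65 ± 0.11), SFG1 (1.81 ± 0.14) and DHR2 (1.57 ± 0.17). Of the genes with a lower difference, CTT1 lay at 14.33 with heat and 14.46 with heat and ISP1. These levels are near the top of the signal, so the size of that difference is not exact. MMP1, an S-methylmethionine permease gene, and MHT1, a homocysteine methyltransferase gene, had higher differences by 1.85 ± 0.27 and 1.69 ± 0.20. Among general stress genes 27 of 31 members had a lower difference and 4 did not pass (28 lower adjusted over the list alone, adjusted p = 2.47e-17, and adjusted p = 0.272 with an estimated correlation). In trehalose and glycogen metabolism 1 of 20 members had a higher difference, 16 had a lower one and 3 did not pass (2 higher and 16 lower adjusted over the list alone, adjusted p = 3.11e-09, and adjusted p = 0.305 with an estimated correlation). In the TCA cycle 12 of 14 members had a lower difference and 2 did not pass (13 lower adjusted over the list alone), and this call held with an estimated correlation (adjusted p = 2.04e-06, and adjusted p = 0.0301 with an estimated correlation). In ribosome biogenesis 41 of 67 members had a higher difference and 26 did not pass (49 higher adjusted over the list alone, adjusted p = 1.68e-09, and adjusted p = 0.724 with an estimated correlation). In amino acid synthesis 2 of 43 members had a higher difference, 26 had a lower one and 15 did not pass (2 higher and 28 lower adjusted over the list alone, adjusted p = 2.92e-08, and adjusted p = 0.642 with an estimated correlation).

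Over all genes, 2231 had an interaction past the threshold in limma, 1188 with a higher and 1043 with a lower difference, 271 of them by at least 2-fold (53 higher and 218 lower). With median centring the balance turned, to 1019 higher and 1238 lower. Of the 1948 that were also called for ISP1 alone, 1898 had an interaction of opposite sign. The interaction and the ISP1 effect share their arrays: across genes r was -0.849, against -0.706 in simulated groups with no effect, and the covariance -0.247 against -0.0110. Lists of independent calls would share 291 genes raised by ISP1 with a lower interaction, where 904 were shared, and 394 in the opposite case, where 994 were. With these control and ISP1 arrays divided 1 against 2, so that no array entered both terms, the covariance was -0.249 to -0.210. The counts of shared calls keep the shared arrays, so part of their excess may come from them. ISP1 effects with and without heat, which share no array, correlated with r = 0.542 across genes, which are not independent replicates (0.501 to 0.554 with 1 array left out). Both comparisons called 564 genes higher and 618 lower, against 251 and 294 for independent lists, and 150 genes in opposite directions.

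Heat was also compared in the presence of ISP1, between cells given both treatments and cells given ISP1 alone. HSP30 rose by 5.04 ± 0.12, TKL2 by 5.03 ± 0.24 and SSA4 by 4.02 ± 0.14, again to 14.95 ± 0.04, near the top of the signal. HO (-4.39 ± 0.10), RNR1 (-3.51 ± 0.08) and ARG3 (-3.25 ± 0.30) fell. Among heat shock proteins and chaperones 30 of 30 members rose (30 rises adjusted over the list alone), with a median of 2.02 (adjusted p = 4.33e-14, and adjusted p = 0.191 with an estimated correlation), beside 2.07 without ISP1. General stress genes had a median of 1.97, beside 2.85 without ISP1, and 29 of 31 members rose and 2 did not pass (29 rises adjusted over the list alone, adjusted p = 6.17e-10, and adjusted p = 0.217 with an estimated correlation). In ribosome biogenesis 67 of 67 members fell (67 falls adjusted over the list alone), with a median of -1.70 (adjusted p = 2.75e-18, and adjusted p = 0.279 with an estimated correlation). In amino acid synthesis 1 of 43 members rose, 41 fell and 1 did not pass (1 rise and 41 falls adjusted over the list alone, adjusted p = 3.87e-12, and adjusted p = 0.218 with an estimated correlation). In phospholipid synthesis 14 of 20 members rose, 2 fell and 4 did not pass (14 rises and 2 falls adjusted over the list alone, adjusted p = 0.00385, and adjusted p = 0.198 with an estimated correlation), with INO1, the inositol phosphate synthase gene, at 1.81 ± 0.08.

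Genes called in limma came to 4206 for heat in the presence of ISP1, 2179 higher and 2027 lower, 1105 by at least 2-fold (504 higher and 601 lower), with 79.4% of genes free of overlap (10% by chance). The poly-A controls averaged 7.33 ± 0.06 with ISP1 and 8.04 ± 0.31 with both (SD, n = 3), and the 3' minus 5' signal of actin was 0.42 ± 0.05 and 0.44 ± 0.01. Across the 4394 genes called for heat without ISP1, the slope of the heat effect with ISP1 on that without was 0.750 (jackknife standard error 0.0434, and 0.726 to 0.767 with 1 array left out). Of the 1488 genes that heat changed at least 2-fold, 1264 changed less where ISP1 was present. The 715 that rose had a median of 1.61 with heat, 1.19 with heat in the presence of ISP1 and 0.65 with ISP1 alone. For the 773 that fell, these medians were -1.55, -1.23 and -0.64. The 260 of the 1488 that were not called for ISP1 alone had medians, in the direction of heat, of 1.40, 1.36 and 0.0969. The genes were chosen by their change without ISP1, which by itself makes that change the larger. Over all genes, with no such choice, the slope was 0.760, which argues against the choice as the reason for a slope under 1. Heat and ISP1, both against the YPD control, shared 1176 genes higher and 1410 lower, against 605 and 739 for independent lists. Their effects correlated with r = 0.716 across genes, against 0.500 in simulated groups with no effect, with a covariance of 0.467 against 0.00553. With the controls divided 1 against 2 between the effects the covariance was 0.418 to 0.488. The counts of shared calls keep the shared controls, so part of their excess could come from them.

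**Figure D1:**
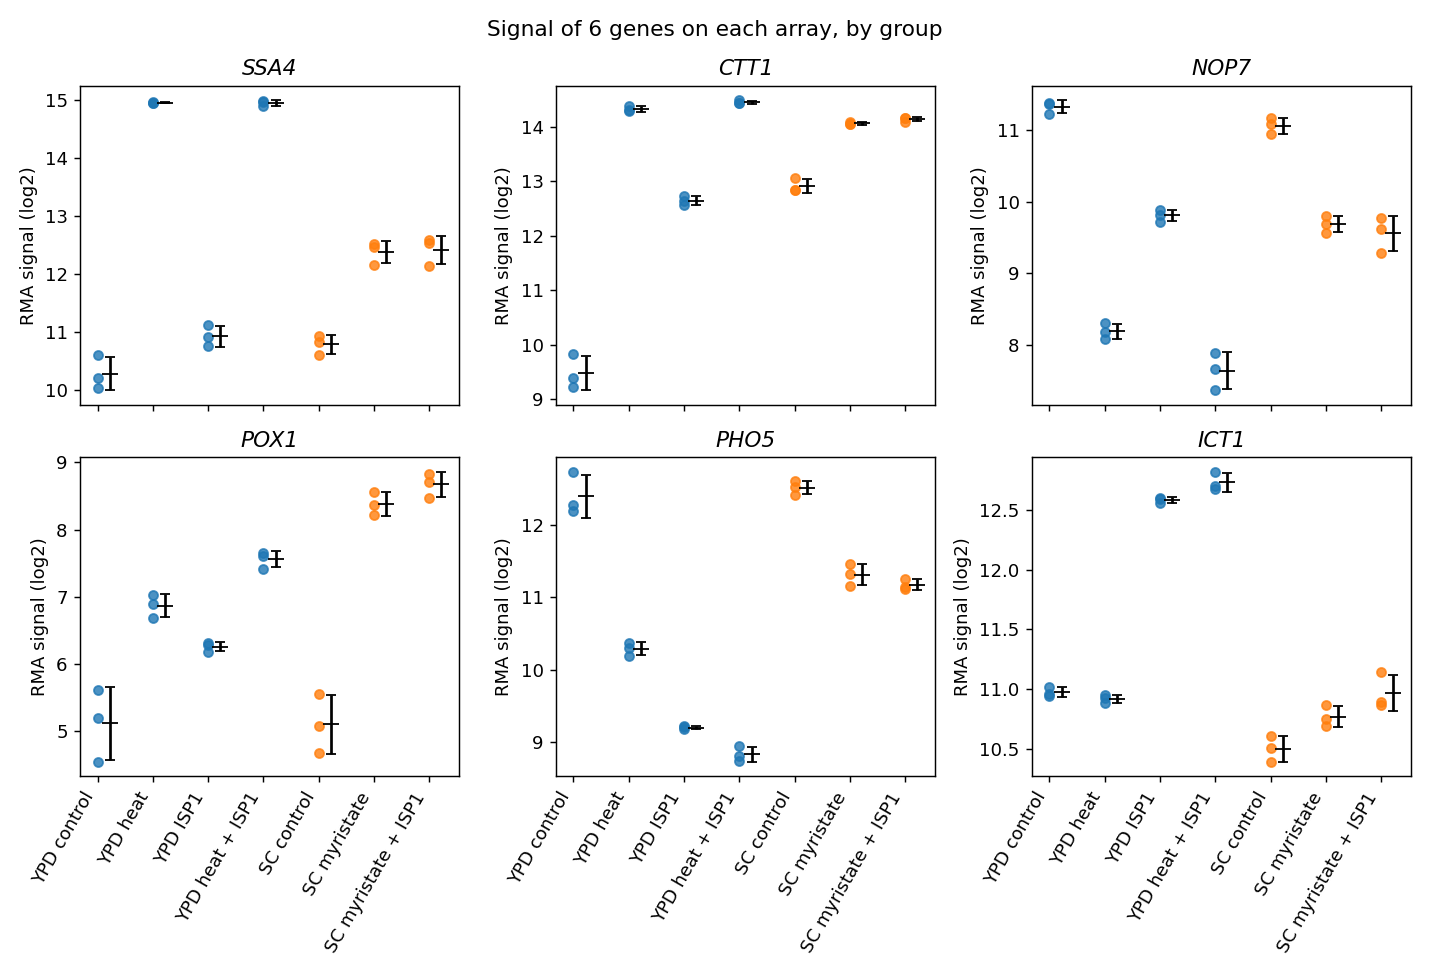
RMA signal (log2, vertical axes) of SSA4, CTT1, NOP7, POX1, PHO5 and ICT1 on each of the 21 arrays, by group (horizontal axes); coloured points are single arrays, blue for YPD and orange for SC, and the black bars beside them are the mean ± SD of 3 arrays. CTT1 lay at 9.48 ± 0.32 in YPD control and 12.65 ± 0.08 with ISP1, and ICT1 at 10.92 ± 0.03 with heat and 12.73 ± 0.08 with heat and ISP1.

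Myristate was compared with control in SC, to ask how cells respond to the added fatty acid. Genes of peroxisomal fatty acid breakdown were among the largest rises. POT1 rose by 4.37 ± 0.25, a 20.6-fold increase, from 7.69 ± 0.13 to 12.06 ± 0.11 (SD, n = 3). POX1 rose by 3.28 ± 0.22, the peroxisomal import gene PEX18 by 2.79 ± 0.14 and IDP3, the peroxisomal isocitrate dehydrogenase gene, by 2.21 ± 0.10. In the list of fatty acid beta-oxidation and peroxisome function 21 of 29 members rose and 8 did not pass (22 rises adjusted over the list alone), with a median of 0.54 (adjusted p = 1.66e-09, and adjusted p = 0.103 with an estimated correlation). FTR1, the iron permease gene, changed by -2.02 ± 0.10 and the hexose transporter gene HXT2 by -1.80 ± 0.26.

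Of the other lipid lists, phospholipid and ergosterol synthesis passed. In phospholipid synthesis 1 of 20 members rose, 10 fell and 9 did not pass (1 rise and 10 falls adjusted over the list alone, adjusted p = 0.0134, and adjusted p = 0.248 with an estimated correlation), with INO1 at 1.26 ± 0.08 and its activator gene INO2 at -1.24 ± 0.11. Fatty acid synthesis, uptake and desaturation did not pass (adjusted p = 0.401), and 4 of 13 members rose, 7 fell and 2 did not pass (4 rises and 8 falls adjusted over the list alone). In ergosterol synthesis 1 of 25 members rose, 9 fell and 15 did not pass (1 rise and 9 falls adjusted over the list alone, adjusted p = 0.0360, and adjusted p = 0.400 with an estimated correlation). Sphingolipid metabolism did not pass (adjusted p = 0.457), and 13 of 34 members rose, 8 fell and 13 did not pass (13 rises and 9 falls adjusted over the list alone), with RSB1 at 1.16 ± 0.13. Among the multidrug resistance transporters 11 of 16 members rose, 1 fell and 4 did not pass (11 rises and 1 fall adjusted over the list alone, adjusted p = 0.000701, and adjusted p = 0.194 with an estimated correlation), with TPO4 at 2.26 ± 0.10 and PDR15 at 2.16 ± 0.15.

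Stress genes rose with myristate. Of the general stress genes 30 of 31 members rose and 1 did not pass (30 rises adjusted over the list alone), with a median of 0.89 (adjusted p = 5.59e-14, and adjusted p = 0.210 with an estimated correlation). NQM1 was at 2.02 ± 0.15. In trehalose and glycogen metabolism 18 of 20 members rose, 1 fell and 1 did not pass (18 rises and 1 fall adjusted over the list alone, adjusted p = 4.78e-08, and adjusted p = 0.248 with an estimated correlation). Among heat shock proteins and chaperones 21 of 30 members rose, 1 fell and 8 did not pass (21 rises and 1 fall adjusted over the list alone), with a median of 0.38 (adjusted p = 8.79e-06, and adjusted p = 0.279 with an estimated correlation) and SSA4 at 1.59 ± 0.14. Of the proteasome genes 31 of 32 members rose and 1 did not pass (31 rises adjusted over the list alone, adjusted p = 4.01e-09, and adjusted p = 0.210 with an estimated correlation). In sulfur assimilation and methionine synthesis 15 of 21 members rose and 6 did not pass (16 rises adjusted over the list alone, adjusted p = 9.25e-06, and adjusted p = 0.279 with an estimated correlation), with MET2 at 2.12 ± 0.21 and STR3 at 2.04 ± 0.31. In ribosome biogenesis 67 of 67 members fell (67 falls adjusted over the list alone), with a median of -0.84 (adjusted p = 2.85e-21, and adjusted p = 0.279 with an estimated correlation). NOP7 fell by 1.37 ± 0.12. Of the histone genes 9 of 9 members fell (9 falls adjusted over the list alone, adjusted p = 0.000908, and adjusted p = 0.339 with an estimated correlation). Of the G1/S genes 13 of 20 members fell and 7 did not pass (13 falls adjusted over the list alone, adjusted p = 0.000621, and adjusted p = 0.351 with an estimated correlation).

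Over all genes, limma called 2849 with myristate, 1451 higher and 1398 lower, 238 of them by at least 2-fold (171 higher and 67 lower). More genes were lower than higher with only the arrays compared (1452 higher and 1471 lower), quantile normalization (1407 higher and 1478 lower), array weights (1590 higher and 1761 lower), no arrays numbered 1 (1294 higher and 1347 lower), no control array 1 (1260 higher and 1450 lower) or no myristate array 3 (1301 higher and 1340 lower). Replicates did not overlap in 62.7% of genes (10% by chance). The 3' minus 5' signal of actin was 0.133 ± 0.015 in SC control and 0.171 ± 0.010 with myristate, without overlap (SD, n = 3). For SRB4 it was 1.85 ± 0.10 and 1.84 ± 0.08, and for SPT15 2.01 ± 0.11 and 2.17 ± 0.13. The other lists that passed, out of 16, were the TCA cycle (median 0.24, adjusted p = 0.00257, and adjusted p = 0.194 with an estimated correlation), the phosphate regulon (-0.29, adjusted p = 0.0272, and adjusted p = 0.351 with an estimated correlation), and cytosolic (-0.11, adjusted p = 0.000395, and adjusted p = 0.712 with an estimated correlation) and mitochondrial (0.11, adjusted p = 0.00663, and adjusted p = 0.530 with an estimated correlation) ribosomal proteins. Across genes, which are not independent replicates, the myristate effect in SC correlated with the heat effect in YPD with r = 0.784 (jackknife standard error 0.0103) and no shared array. Heat and myristate shared 1238 genes called higher and 1202 called lower, against 577 and 571 for independent lists, and 93.9% of the 2598 genes called in both had the same sign. The myristate effect and the ISP1 effect in YPD, which share no array either, correlated with r = 0.739 and shared 1062 higher and 1124 lower genes, against 405 and 464.

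**Figure D2:**
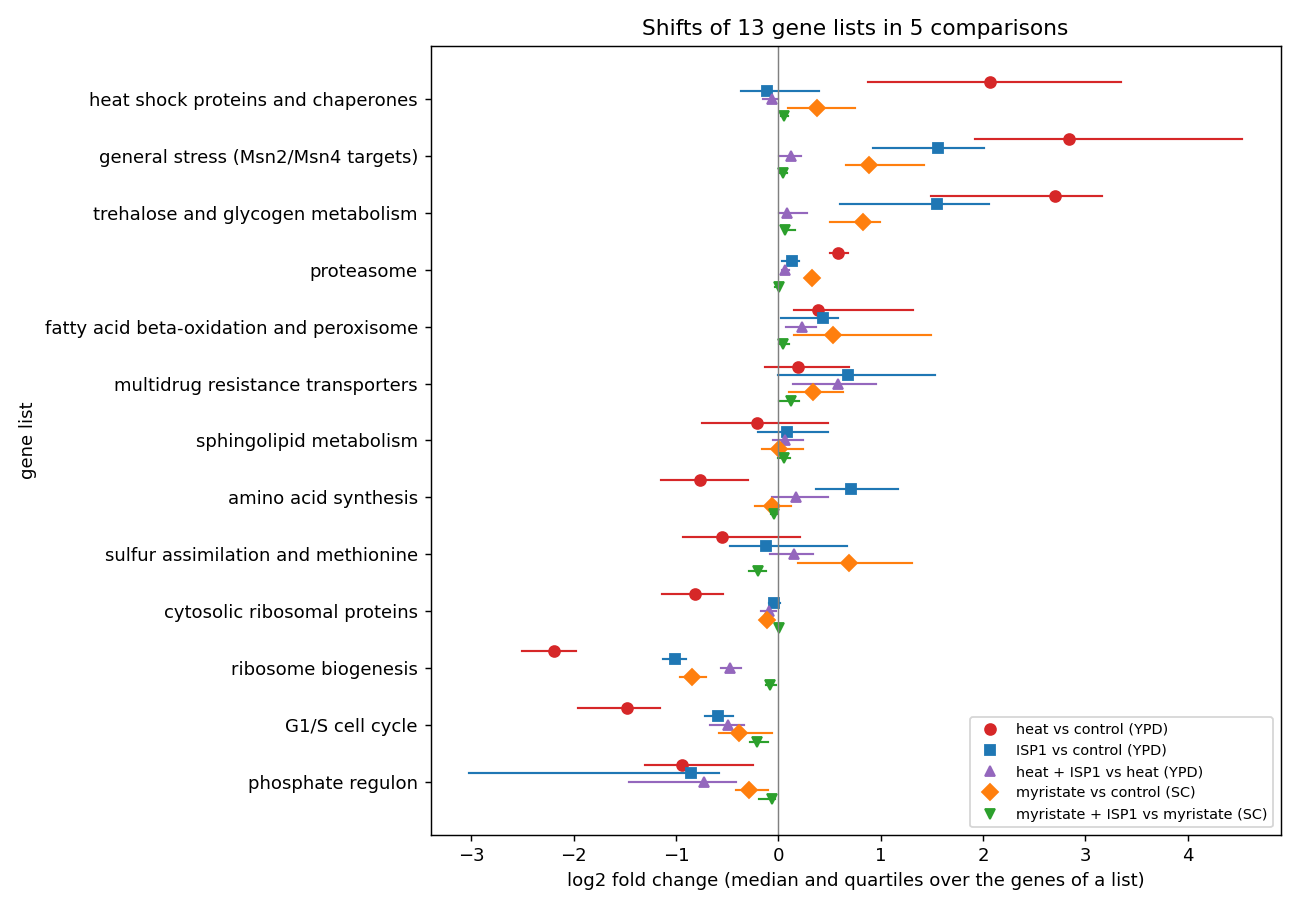
Shifts of 13 gene lists (vertical axis) in 5 comparisons, as log2 fold change (horizontal axis); symbols are medians and lines the quartiles over the genes of a list. Ribosome biogenesis lay at -2.20 with heat, -1.01 with ISP1 and -0.84 with myristate, and at -0.08 for ISP1 added to myristate.

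ISP1 was added to myristate in SC, and these cells were compared with cells given myristate alone. VHR1, a transcription factor gene of the biotin response, rose by 0.48 ± 0.08 (adjusted p = 0.0363) and was the 1 gene of 5449 that limma called. An unadjusted p under 0.05 was found for 349, where a share of 0.05 of all genes is expected with no effect. The call of VHR1 did not hold with only these 6 arrays (adjusted p = 0.276). It was lost without myristate array 1 (0.118), 2 (0.134) or 3 (0.0616), and without myristate and ISP1 array 2 (0.274) or 3 (0.210). Over all its settings the adjusted p ran from 0.00161 to 0.276. POX1 was at 0.29 ± 0.22 (adjusted p = 0.966), TPO4 at 0.50 ± 0.10 (0.15) and CTT1 at 0.08 ± 0.10 (0.998). The median standard error over genes was 0.0795. A simulated change of 0.5 was recovered for 90% of genes in this comparison, and one of 0.25 for 58%. That simulation held 200 changed genes, which eases the adjusted threshold, so these shares do not hold where 1 gene passes. TPO4, at 0.50, was not called. Replicates did not overlap in 13% of genes, where chance gives 10%, and 43 genes were called with array weights.

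Small shifts of whole lists passed with the preset correlation for 12 of 31 lists and for none with an estimated one. Sulfur assimilation and methionine genes had a median of -0.20 (adjusted p = 1.19e-13, and adjusted p = 0.0901 with an estimated correlation) and G1/S genes one of -0.21 (adjusted p = 1.19e-13, and adjusted p = 0.0901 with an estimated correlation), with 3 of the 20 G1/S genes falling when adjusted over the list alone. Multidrug resistance transporters were at 0.12 (adjusted p = 0.000857, and adjusted p = 0.130 with an estimated correlation), and 2 of 16 rose when adjusted over the list alone. The sphingolipid genes had a median of 0.06 (adjusted p = 0.00792, and adjusted p = 0.295 with an estimated correlation), and 1 of 34 rose when adjusted over the list alone. Phospholipid synthesis (-0.07, adjusted p = 1.34e-05, and adjusted p = 0.0645 with an estimated correlation), ribosome biogenesis (-0.08, adjusted p = 1.43e-05, and adjusted p = 0.873 with an estimated correlation) and the phosphate regulon (-0.06, adjusted p = 0.00338, and adjusted p = 0.295 with an estimated correlation) lay lower.

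Cells with myristate and ISP1 were also set against the SC control, which gives the net change with both. POT1 rose by 4.35 ± 0.25, POX1 by 3.57 ± 0.22, TPO4 by 2.75 ± 0.10 and BAG7 by 2.53 ± 0.15, while FTR1 changed by -1.97 ± 0.10 and INA1 by -1.65 ± 0.16. In fatty acid beta-oxidation and peroxisome function 24 of 29 members rose, 1 fell and 4 did not pass (24 rises and 1 fall adjusted over the list alone, adjusted p = 1.29e-08, and adjusted p = 0.147 with an estimated correlation). Of the general stress genes 29 of 31 members rose and 2 did not pass (30 rises adjusted over the list alone, adjusted p = 2.96e-12, and adjusted p = 0.240 with an estimated correlation). In ribosome biogenesis 67 of 67 members fell (67 falls adjusted over the list alone, adjusted p = 1.93e-21, and adjusted p = 0.251 with an estimated correlation). For the G1/S genes 16 of 20 members fell and 4 did not pass (18 falls adjusted over the list alone, adjusted p = 1.64e-06, and adjusted p = 0.240 with an estimated correlation). Genes called in limma numbered 3102, 1646 higher and 1456 lower, 304 by at least 2-fold (212 higher and 92 lower), with 62.0% of genes free of overlap (10% by chance). The balance turned with quantile normalization (1530 higher and 1639 lower), without the arrays numbered 1 (1488 higher and 1571 lower) and without control array 1 (1444 higher and 1494 lower). The 3' minus 5' signal of actin was 0.133 ± 0.015 in SC control and 0.172 ± 0.022 with both, without overlap (SD, n = 3). For SRB4 it was 1.85 ± 0.10 and 1.83 ± 0.09, and for SPT15 2.01 ± 0.11 and 2.19 ± 0.25. The design holds no SC group with ISP1 alone, so an interaction of ISP1 and myristate was not fitted.

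Whether the ISP1 difference itself changed between myristate-treated and heated cells was tested directly, although the medium differs as well. The difference with myristate was higher for SPL2 (1.97 ± 0.14), PHO11 (1.33 ± 0.11) and PHO5 (1.31 ± 0.15), which ISP1 lowered in heated cells. It was lower for YGR035C (-2.30 ± 0.31), RTA1 (-2.01 ± 0.19), RSB1 (-1.72 ± 0.18) and ICT1 (-1.61 ± 0.10), which ISP1 raised in heated cells. In the phosphate regulon 11 of 13 members had a higher difference and 2 did not pass (11 higher adjusted over the list alone), and this call held with an estimated correlation (adjusted p = 2.35e-13, and adjusted p = 0.00792 with an estimated correlation). So did that of the multidrug resistance transporters, where 1 of 16 members had a higher difference, 9 had a lower one and 6 did not pass (1 higher and 9 lower adjusted over the list alone, adjusted p = 1.16e-06, and adjusted p = 0.0329 with an estimated correlation), with PDR15 at -1.13 ± 0.22 and PDR16 at -0.93 ± 0.09. In ribosome biogenesis 10 of 67 members had a higher difference and 57 did not pass (18 higher adjusted over the list alone, adjusted p = 7.59e-11, and adjusted p = 0.452 with an estimated correlation). For the G2/M and M/G1 genes 9 of 19 members had a higher difference and 10 did not pass (12 higher adjusted over the list alone, adjusted p = 1.16e-06, and adjusted p = 0.156 with an estimated correlation). In amino acid synthesis 1 of 43 members had a higher difference, 14 had a lower one and 28 did not pass (2 higher and 19 lower adjusted over the list alone, adjusted p = 1.16e-06, and adjusted p = 0.445 with an estimated correlation).

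For this difference of differences limma called 622 genes, 330 higher and 292 lower with myristate, 67 by at least 2-fold (22 higher and 45 lower), and 1705 with array weights. The balance turned with only the arrays compared (229 higher and 248 lower), with quantile normalization (365 higher and 384 lower), and without myristate array 1 (227 higher and 228 lower) or myristate and ISP1 array 2 (276 higher and 292 lower). Across genes, which are not independent replicates, the ISP1 effect in heated cells and that in myristate-treated cells correlated with r = 0.388 (jackknife standard error 0.128), with no shared array. Leaving out 1 array moved r between 0.292 and 0.429. VHR1, the gene called with myristate, also rose with ISP1 alone (1.73 ± 0.08) and with ISP1 in heated cells (1.49 ± 0.08).

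The control groups of both media were compared to find how far levels can be set side by side across media. ADE17, of purine synthesis, was higher in SC by 4.90 ± 0.11, a 29.9-fold difference, and INO1 by 4.42 ± 0.08. CTT1 (3.44 ± 0.10) and GPH1 (3.54 ± 0.12) were higher in SC too. The peptide transporter gene PTR2 (-4.36 ± 0.08), the decarboxylase gene ARO10 (-3.06 ± 0.14), the serine and threonine deaminase gene CHA1 (-2.41 ± 0.08) and RSB1 (-2.16 ± 0.13) were lower. In phospholipid synthesis 16 of 20 members rose, 2 fell and 2 did not pass (16 rises and 2 falls adjusted over the list alone), and this call held with an estimated correlation (adjusted p = 2.45e-11, and adjusted p = 0.00239 with an estimated correlation), with OPI3 at 2.32 ± 0.08. The TCA cycle call held as well: 12 of 14 members rose and 2 did not pass (12 rises adjusted over the list alone, adjusted p = 1.42e-08, and adjusted p = 0.00320 with an estimated correlation). Of the general stress genes 30 of 31 members rose and 1 did not pass (30 rises adjusted over the list alone, adjusted p = 2.83e-25, and adjusted p = 0.0591 with an estimated correlation). In trehalose and glycogen metabolism 13 of 20 members rose, 2 fell and 5 did not pass (13 rises and 2 falls adjusted over the list alone, adjusted p = 1.02e-05, and adjusted p = 0.478 with an estimated correlation). In iron uptake and homeostasis 2 of 26 members rose, 20 fell and 4 did not pass (2 rises and 20 falls adjusted over the list alone, adjusted p = 0.00283, and adjusted p = 0.478 with an estimated correlation).

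Between the controls limma called 3258 genes, 1029 higher and 2229 lower in SC, 333 by at least 2-fold (221 higher and 112 lower), with 67.8% of genes free of overlap (10% by chance). The median difference of all genes was -0.13, against which these values are read. Medium went together with array processing: the hybridization controls spiked into the arrays averaged 11.1 on the 9 SC arrays and 11.7 on the 12 YPD arrays, and the poly-A controls 6.83 and 7.61. The 3' minus 5' signal, a sign of RNA quality, was 0.13 ± 0.01 in SC control and 0.38 ± 0.02 in YPD control for actin (SD, n = 3) and 1.85 ± 0.10 and 2.65 ± 0.11 for SRB4. For SPT15 it was 2.01 ± 0.11 and 2.00 ± 0.18, so that gene showed no such difference. Medium, processing and RNA quality cannot be told apart here. Cell wall integrity targets, the respiratory chain, glycolysis, the phosphate regulon and thiamine and pyridoxine synthesis passed in SC against YPD with the preset correlation (adjusted p = 0.0143, 0.0128, 0.00613, 0.0153 and 0.0282). With quantile normalization over the genes of the species none of these 5 did, at adjusted p = 0.0505, 0.135, 0.131, 0.0505 and 0.0505, nor did any with an estimated correlation (adjusted p = 0.563, 0.713, 0.563, 0.478 and 0.478).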

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

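The comparisons, list tests, counts of genes called in other splits and the correlation of ISP1 effects with heat and with myristate were set before their results were seen. Of the tests of explanations, that of a signal ceiling for genes under log2 12 was set before its result was seen, and the others were chosen after, as were the tests of probe sets outside the genes.

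The heat by ISP1 interaction was singled out because its test of the difference passed for 2231 genes. Of 100 splits of these arrays, 2 gave as many, the real one included (highest other 2232). The count followed the ISP1 and control arrays: splits with only these as labelled gave 1916 to 2232 genes, those with only the heat pair as labelled 64 to 163 and those with neither at most 1. These splits therefore decide nothing on chance for the interaction. List medians of the difference were -1.32 for general stress, -1.25 for trehalose and glycogen, -0.12 for mitochondrial ribosomal proteins, 0.56 for ribosome biogenesis, -0.31 for cell wall integrity, -0.49 for amino acid synthesis, -0.36 for the respiratory chain and -0.40 for the TCA cycle. Except for the TCA cycle, none of these calls held with an estimated correlation, where their adjusted p ran from 0.272 to 0.724. Genes with the highest log2 differences were MMP1 1.85, SFG1 1.81, SPS100 1.80, PHO5 1.73, MHT1 1.69, PHO11 1.65, LRP1 1.61, DHR2 1.57, YLL053C 1.44 and NRG2 1.43. Those with the lowest were ARG3 -3.35, RTC2 -3.33, GPH1 -3.06, CTT1 -3.04, EGO4 -3.02, TMA10 -3.02, RTC3 -2.996, SOL4 -2.79, PGM2 -2.76 and CYB2 -2.73. With heat CTT1 lay at 14.33, EGO4 at 13.92, TMA10 at 13.78 and SOL4 at 13.78, levels for which a signal ceiling stays open below.

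The pattern behind it is that the ISP1 effect was smaller in heated cells across genes, though not for all of them. Of 1948 genes called for the interaction and for ISP1 alone, 1898 had an interaction of opposite sign. ORM2 kept its rise (interaction 0.05 ± 0.10, adjusted p = 0.741 in limma). The multidrug list was not called (adjusted p = 0.488 in camera), but its members were split. Of its 16 members 3 had a higher difference, 5 had a lower one and 8 did not pass. A further 220 interaction genes were called for ISP1 only under heat. Noise of the control arrays, which enter both terms, would leave a slope of 1 between ISP1 effects that share no array, and the slope was 0.349 (jackknife standard error 0.0549). A signal ceiling would spare dimmer genes, but the 190 genes raised at least 2-fold by ISP1 alone and under log2 12 in heated cells kept a median share of 0.263 of their rise; for the 113 brighter ones (0.0928) a ceiling stays open. That heat had already moved the same genes would spare those with a heat change under 0.5 log2, which includes small rises and falls. The 57 such genes raised at least 2-fold by ISP1 alone kept 0.208 (quartiles 0.0708 to 0.498). For the 221 genes that ISP1 alone and heat each raised at least 2-fold (0.147) this explanation stays open. Genes that ISP1 lowered were not tested for it, nor for a floor of the signal, so both stay open for them. Array-wide scaling left by the authors' normalization would give a slope of 1 after quantile normalization over S. cerevisiae probe sets, but it was 0.357 (jackknife standard error 0.0527), while the probe-level steps of RMA and a biological effect of heat on the response to ISP1 stay open.

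The ISP1 difference between myristate-treated and heated cells was singled out as well, with 622 genes past its test. Of 100 splits, 10 gave as many, with a highest other of 1009. Here the count followed the heat pair, with 651 to 1009 genes in splits with only that pair as labelled, 0 with only the myristate pair and at most 1 with neither, so these splits decide nothing on chance either. List medians of the difference, with myristate minus with heat, were 0.13 for heat shock proteins and chaperones, 0.0945 and -0.0852 for cytosolic and mitochondrial ribosomal proteins, 0.39 for ribosome biogenesis, 0.15 for ergosterol, -0.14 for beta-oxidation and -0.12 for phospholipid synthesis. Others were 0.31 for cell wall integrity, -0.22 for amino acid synthesis, -0.32 for sulfur and methionine, 0.13 for the respiratory chain, 0.70 for the phosphate regulon and -0.40 for multidrug resistance. G1/S genes lay at 0.32, G2/M and M/G1 genes at 0.49 and mating-type a markers at 0.44. Of these 16, the phosphate and multidrug calls held with an estimated correlation and the rest had adjusted p of 0.156 to 0.647. The highest gene differences were SPL2 1.97, YOR072W-B 1.64, YDR222W 1.55, CHA1 1.39, PHM6 1.35, PHO11 1.33, PHO5 1.31, PHO3 1.31, YNL042W-B 1.24 and KDX1 1.23, of which YNL042W-B lay under the background limit of 4.84 in both myristate groups (4.65 and 4.82 with ISP1), so its size is not exact. The lowest were YGR035C -2.30, SPS100 -2.09, RTA1 -2.01, OSW2 -1.85, PRM4 -1.75, RSB1 -1.72, DIA1 -1.65, BAG7 -1.61, ICT1 -1.61 and YHI9 -1.59.

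The pattern there is that limma called 1 gene for ISP1 in myristate-treated cells. Too little precision on those arrays to see effects as large as in heated cells would leave a shift of about that size. The 78 genes that ISP1 changed at least 2-fold in heated cells shifted by a median of 0.167 (quartiles 0.0319 to 0.255) against 1.24, with a median standard error of 0.121. That argues against missed effects of the heated size, but smaller ISP1 effects that missed the threshold stay open. For ISP1 being absent from those arrays, the correlation with the ISP1 effect in heated cells was 0.388 and 63 of the 78 genes shifted as in heated cells, but simulated groups with no effect (-0.0471 to 0.0567) vary less than the other 9 splits (at most 0.296), and 10 splits are too few for a share under 0.05, so this stays open. A candidate explanation is that these genes had already moved. The 454 genes that ISP1 alone changed at least 2-fold lay, in SC with myristate, a median of 1.32 from YPD control in the ISP1 direction. ISP1 itself gave 1.33, although YPD controls enter both and medium goes with array processing. Against the SC control, which shares no array with the choice of genes, the myristate value was smaller, at 0.838. The SC control lay 0.454 from YPD control in that direction. For the 78 genes of heated cells the value was 0.568 (quartiles -0.123 to 1.49), which decides nothing, and the time of ISP1 treatment, which the labels leave out, stays open too.

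A signal outside the genes tested was that of ribosomal RNA probe sets. The probe set d of 25S rRNA was higher in heated cells than in control by 5.65 ± 0.43 (adjusted p = 1.03e-09 in limma), at 11.8 against 6.16, and lay at 6.65 in heated cells with ISP1. Probe set e of 25S rRNA lay at 14.86 with heat (adjusted p = 4.67e-10 against control at 11.04) and 14.46 with heat and ISP1 (adjusted p = 0.430 against heat alone), both near the top of the signal, where sizes are not reliable, and probe set a was at 0.01 with heat (adjusted p = 0.986). Sets b and c were higher with heat by 1.82 and 1.84 and, in heated cells, lower with ISP1 by 1.79 and 1.72. More ribosomal RNA of all kinds would raise the 18S probe sets on every heat array, but their median change was 2.18, 0.0158 and -0.429 on replicates 1, 2 and 3. A single aberrant array is argued against by the lowest heat array, which lay 2.20 above the highest array of the other groups. Ribosomal RNA signal also differed between the media. In SC against YPD control the 18S sets a and c were higher by 2.92 and 4.18 (adjusted p = 0.000633 and 6.77e-08 in limma), and the other 18S sets did not pass. All 25S sets were higher, by 0.92 to 1.60 (adjusted p of 0.0139 to 0.0314 in limma). No biological explanation was tested. Probe sets without a gene name were a further signal outside the comparisons. With adjustment over all probe sets, 185 of the 395 above the background limit passed in heat against control, 62 by at least 2-fold. By comparison, 80.6% of the genes tested passed. So did 154 of the 1746 other-species probe sets (8.82%), 0 of them by at least 2-fold, so probe sets at background can pass too.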

How the results depend on the processing

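Leaving out all arrays numbered 1 was chosen after seeing the data, and every other setting was chosen before. Genes named only as members of a list were not run under these settings, so named genes here are the others. No named gene or list past its test changed sign under any setting run, but the balance of higher and lower genes turned under 1 setting for heat, 7 for heat with ISP1 against heat, 1 for the interaction, 6 for myristate, 1 for myristate with ISP1 against myristate, 3 for the same against SC control and 4 for ISP1 with myristate against with heat. The 2-fold minimum turned it for ISP1, heat with ISP1 against ISP1, the interaction, ISP1 with myristate against with heat, and the controls. Of 296 results for named genes, 8 lost and 13 gained the call somewhere, and 131 of 138 list calls were lost somewhere, mostly with the estimated correlation in the set test, which left 0, 0, 2, 0, 1, 0, 0, 0, 2 and 2 lists in the order heat, ISP1, heat with ISP1 against heat, heat with ISP1 against ISP1, interaction, myristate, myristate with ISP1 against myristate, the same against SC control, ISP1 with myristate against with heat, and SC against YPD control. Requiring a change of at least 2-fold left 1488, 454, 78, 1105, 271, 238, 0, 304, 67 and 333 genes in that order, by construction. Leaving out 1 array gave 4250 to 4292, 3076 to 3174, 1360 to 1693, 4019 to 4080, 1966 to 2316, 2473 to 2710, 0 to 2, 2806 to 3000, 455 to 705 and 2778 to 3070 genes. With array weights limma called 2960 genes for heat with ISP1 against heat, 1705 for ISP1 with myristate against with heat and 43 for myristate with ISP1 against myristate, and the cause was not tested. For that last comparison limma called 3 genes with quantile normalization over S. cerevisiae probe sets, 2 with median centring and 22 without the arrays numbered 1, and the cause was not tested. It called 0 with only the arrays compared (392 at unadjusted p under 0.05, where 0.05 of all genes are expected by chance). Without 1 array it called 0 without myristate replicates 1, 2 and 3 (257, 280 and 314 unadjusted) and without myristate with ISP1 replicates 2 and 3 (248 and 397), and 2 without replicate 1 of that group. With the replicate block it called 0 (374 unadjusted), though the numbers do not pair these arrays. Where they do pair, the block gained LCB2 in heat with ISP1 against heat and HSP26 in ISP1 against control, gained the list of mating-type a markers in heat with ISP1 against heat and changed no other named-gene or list call. Where they do not, it lost VHR1 (adjusted p = 0.0801) and the list of fatty acid synthesis in heat against control, gained HSP26 in SC against YPD control (0.0454) and the proteasome list in ISP1 with myristate against with heat (0.0494, and 0.0493 with dim genes left out), and kept every other count within 1.5 times. The heat and myristate effects had a Spearman correlation of 0.769 across genes against r = 0.784. With quantile normalization over S. cerevisiae probe sets 7 lists passed between the controls, in place of 12, and with median centring the share of rises there was 41.0%, in place of 31.6%. Signal limits genes near the background of 4.84 and those near the top, such as SSA4.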

Other observations

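The gene and list tests and the counts in other splits were set before their results were seen, and no explanation is tested in this part.

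The labels do not give the mating type of the cells. With heat 4 of 4 alpha markers fell (4 falls adjusted over the list alone, adjusted p = 0.0249, and adjusted p = 0.383 with an estimated correlation), with STE3 at -3.19 ± 0.11. For the a markers 5 of 7 members rose and 2 did not pass (5 rises adjusted over the list alone, adjusted p = 0.141), with ASG7 at 2.36 ± 0.18. Among hexose transporters HXT3 (-2.09 ± 0.11) and HXT1 (-1.56 ± 0.19) fell with heat while HXT7 (1.47 ± 0.11) rose, and 6 of 13 members rose, 4 fell and 3 did not pass (6 rises and 4 falls adjusted over the list alone, adjusted p = 0.660). In iron uptake and homeostasis 12 of 26 members rose, 10 fell and 4 did not pass (12 rises and 11 falls adjusted over the list alone) with heat, where median and test differed in sign (adjusted p = 0.660), with the cell wall mannoprotein gene FIT2 at 2.19 ± 0.21. With myristate 6 of 26 members rose, 7 fell and 13 did not pass (6 rises and 7 falls adjusted over the list alone) in the iron list (adjusted p = 0.563), and the oxidase gene FET3 fell by 1.04 ± 0.13.

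Of the thiamine and pyridoxine synthesis genes 4 of 14 members rose, 5 fell and 5 did not pass (5 rises and 5 falls adjusted over the list alone) with ISP1, where median and test differed in sign (adjusted p = 0.976). SNZ1 rose by 2.33 ± 0.19 with ISP1 and was higher in SC than in YPD control by 2.04 ± 0.19. Among permeases of amino acids and nucleobases 6 of 20 members rose, 7 fell and 7 did not pass (6 rises and 7 falls adjusted over the list alone) with ISP1 (adjusted p = 0.833), with the proline permease gene PUT4 at 1.62 ± 0.11. Of the meiosis and sporulation markers 8 of 16 members rose, 3 fell and 5 did not pass (8 rises and 3 falls adjusted over the list alone) with heat (adjusted p = 0.355), and SPS4 fell by 2.46 ± 0.18. In glycolysis and fermentation 11 of 16 members rose, 1 fell and 4 did not pass (11 rises and 1 fall adjusted over the list alone) with heat (adjusted p = 0.101), with TDH1 at 1.88 ± 0.08.

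Other splits of the 6 arrays of a comparison make 10, too few for a share under 0.05. As many genes as in the real split were called in 1 split of 10, the real one, for each of the 8 comparisons of 2 groups. The real count and the highest other were 4394 and 0 for heat, 3331 and 1 for ISP1, 1784 and 7 for heat with ISP1 against heat and 4206 and 0 for heat with ISP1 against ISP1 in limma. In SC they were 2849 and 0 for myristate, 1 and 0 for myristate with ISP1 against myristate and 3102 and 0 for the same cells against control, and between the controls 3258 and 0.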
